A study of Homo sapiens with 2 samples.

How the data were processed

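The series profiled chromatin contacts of HCC1599 cells, an established line of triple-negative breast cancer, by HiChIP against SMC1a. HiChIP ligates neighbouring pieces of chromatin in the nucleus after cutting with a restriction enzyme, here MboI, and then pulls down the pieces that carry a chosen protein. SMC1a is a core subunit of cohesin, the ring complex that holds chromatin loops together. Per the labels, 1 library came from untreated cells and 1 from cells kept for 72 hours in 1 µM compound E, a gamma-secretase inhibitor (GSI) that blocks the cleavage that releases active Notch. Per the labels' protocols, libraries were made with Tn5 transposase and read from both ends with reads of 38 bp.

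The deposited lists are the authors' own contact calls. Per the submitters' processing notes, HiC-Pro, Juicer 1.7.6 and MACS were used with the hg19 genome build, and no role or order is given for them. The lists' names give an FDR of 0.05 and a maximum distance of 2 Mb. The tool behind that FDR is not given in the sources used here. The lists have no header. Each row of the deposited lists holds an anchor, a partner anchor and a whole number, and each contact stood in its list from both sides, so each was used once. The deposited number was read as the raw count of read pairs that join 2 anchors, since it was whole, at least 2, and its lowest value fell from 7 for contacts under 5 kb to 2 for contacts over 1 Mb. No name in the lists states this quantity, so every read number rests on that reading. The lists held contacts within chromosomes 1 to 22 and X only. Anchors of the 2 lists were not the same intervals: 393 anchors and 0 contacts had identical coordinates.

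The groups follow the labels. The name given to the untreated list mentions DMSO while its label says untreated, so whether a vehicle was added is open, and the label was used. There are no replicates: each group is 1 library, so no test was run and no p-value is given, and no difference has a replicate check. Intervals are 95% intervals that cover counting error only: exact Poisson for a count, Clopper-Pearson for a share, and the exact conditional binomial for a ratio of 2 counts. PCR reads without molecular identifiers are not independent molecules. In windows each read pair counts at both of its ends, so intervals of window values are also somewhat too narrow.

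Distance is the distance between the midpoints of the 2 anchors. Ratios are GSI-treated over untreated after dividing by the summed contact reads of each list, on the log2 scale. A value of 0.5 was added to counts where windows or bin pairs were ranked or counted, where an SD or correlation was taken over windows, in the ratios of shared bin pairs, and in the log2 ratios that set named windows beside their alternatives. Contacts were called shared when both midpoints lay within 5 kb or 10 kb of a contact of the other list, with the other list moved by 1 to 5 Mb as a background. Exact identity of both anchors was the rule set beforehand, and it could not match anything here. Contact strength was compared in 10 kb bin pairs that both lists held, a choice made after seeing the data. The value these pairs give with no change was taken, also after seeing the data, from 20 random splits of the untreated reads and from 20 thinned untreated lists set against the whole list. Read ends were summed in windows of 50 kb with at least 200 ends over both lists and in windows of 1 Mb with at least 2000. Pairs of 250 kb windows that were at least 2 windows apart were compared where they held at least 500 reads. The 1 Mb windows that each held more than 1% of the untreated read ends are called the contact-dense block.

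The windows named were chosen by a rule set before the data were examined: the 10 highest and the 10 lowest 50 kb windows whose interval excluded 0, and the 5 best connected anchors of each list. The 1 Mb windows, runs of windows, bin pairs, the anchors outside the contact-dense block and the chromosome 8 window described at the end of the report were chosen after their values were seen. The chromosome 8 window was picked as the 250 kb window that came up most often, 3 times, among the 20 lowest bin pairs. Coordinates are in hg19 as the lists give them, counted from 1. The gene table at hand is on another build, so no gene was placed on a contact. For that reason the promoter comparison, the 17 gene lists fixed beforehand (Notch targets, cell type markers, cell cycle and others) and the named Notch genes were not analysed here, and 50 kb windows took the place of promoters, as the design had foreseen.

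The window step was tested on simulated counts for all 29325 windows, with 50 windows planted at each of 4-fold, 2-fold, 0.5-fold and 0.25-fold. At each size 100% of the planted windows had an interval on the planted side of 0, and 95.8% of the 29125 unchanged windows had an interval that held 0. The counts were drawn as Poisson, so double counting of ends and PCR copies were not part of them. The overlap step found 100% of 15002 planted matches among 50000 contacts. Planted midpoints were moved by less than the 5 kb tolerance, so that outcome was fixed and checks only the code. Alternatives tried were a minimum of 4 reads, contacts of 20 kb or more, binomial thinning of the untreated list (planned at the ratio of the 2 totals; after seeing the data also to about as many listed reads), numbers of contacts in place of reads, anchors joined into 25 kb windows, and other scalings. Thinning used a fixed seed, with 20 draws for whole lists and 100 for single regions. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.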

Results

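The study asked how Notch signalling bears on long-range contacts between regulatory elements, and in this part set untreated HCC1599 cells beside cells kept in a gamma-secretase inhibitor, which was used to switch Notch off. The untreated list held 1084214 contacts (95% interval 1082174 to 1086257) with 5172528 contact reads. The GSI-treated list held 652513 contacts (650931 to 654098) with 2528596 reads, 60.2% of the contacts and 48.9% of the reads of the untreated list. Contacts carried a mean of 4.77 reads in the untreated list and 3.88 in the GSI-treated list. They joined 585892 and 456860 anchors, which covered 973 and 708 Mb of the genome. The sequencing depth itself is not given in the sources used here; with more listed reads, values of the untreated list have the smaller counting error. Thinned to about as many listed reads as the GSI-treated list, the untreated list kept 644129 contacts, of which the GSI-treated number was 101%.

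The first comparison asked how far contacts reach. The median contact spanned 840 kb in the untreated list and 870 kb in the GSI-treated list, and contacts over 1 Mb made up 42.3% (42.2 to 42.4%) and 43.3% (43.1 to 43.4%). By reads, the GSI-treated list was higher at both ends of the range. Contacts under 5 kb held 6.30% of the untreated reads and 8.48% of the GSI-treated reads, a log2 ratio of 0.43 (0.42 to 0.44). Contacts of 1 to 2 Mb held 23.2% and 26.7%, a log2 ratio of 0.20. Contacts of 100 to 200 kb held 10.6% and 8.83%, with the lowest log2 ratio of the bands, -0.26 (-0.27 to -0.25). Thinned to about as many listed reads, the untreated list had a median of 680 kb. Thinned at the ratio of the 2 totals, which left fewer listed reads, it had 530 kb. Contacts of 1 to 2 Mb had a median of 2 reads in both lists, the lowest number listed. Thinning a called list therefore removes long contacts first and can add none. Both medians fall by construction and do not show the distances of a shallower library. Among contacts of at least 4 reads the order of the medians turned, to 316 kb in the untreated list and 242 kb in the GSI-treated list.

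**Figure D1:**
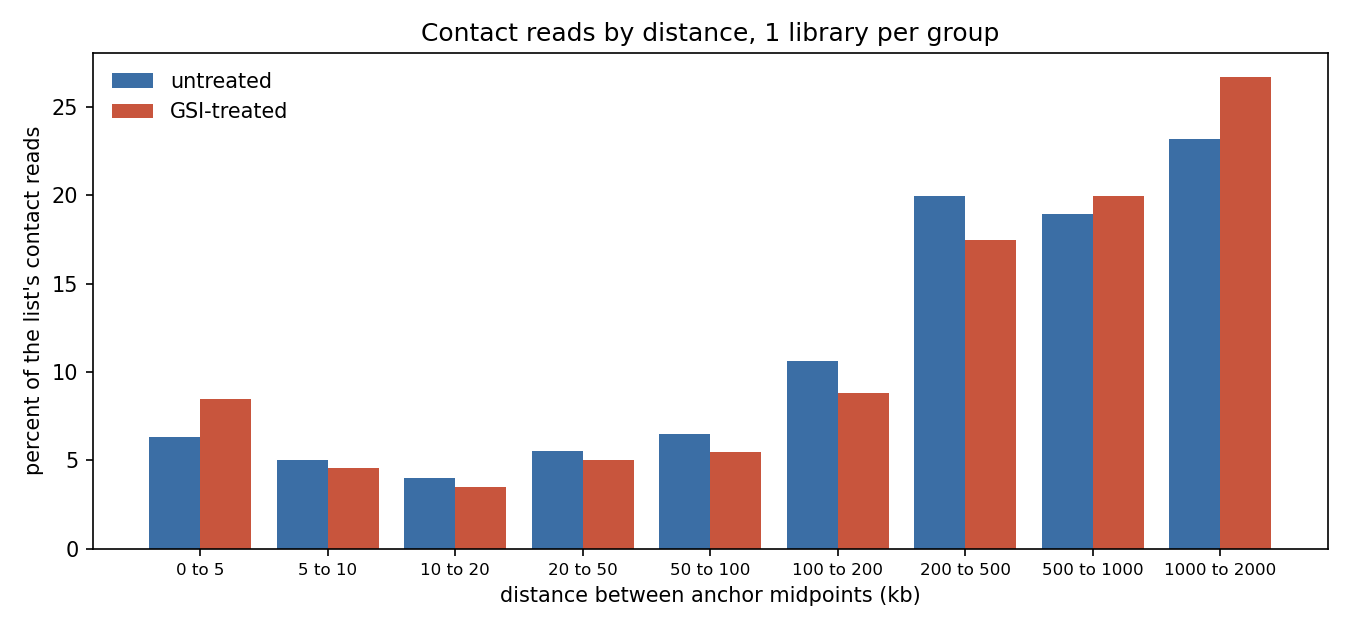
Percent of each list's contact reads (vertical axis) by distance between anchor midpoints in kb (horizontal axis), 1 bar per library. The GSI-treated bar is higher under 5 kb (8.48% against 6.30%) and above 500 kb, and lower from 5 to 500 kb.

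The next comparison asked which contacts both libraries listed. Within 5 kb at both midpoints, 7.71% (7.66 to 7.76%) of untreated contacts had a GSI-treated counterpart, and 11.4% (11.3 to 11.5%) of GSI-treated contacts had an untreated one. With the other list moved along the chromosome these shares were 1.51% and 2.44%. Within 10 kb they were 17.8% and 24.4%, against 5.23% and 8.11% for moved lists. After thinning the untreated list at the ratio of the totals, the shares within 5 kb were 10.9% and 9.29%, so their order turned. Strong contacts were shared far more often than weak ones. Of untreated contacts with 20 or more reads, 39.5% had a counterpart within 5 kb, against 2.24% of those with 2 reads. With the other list moved, these shares were 7.48% and 1.11%. For the GSI-treated list the same shares were 48.7% and 4.24%, and 10.6% and 1.89% with the other list moved. Read number was tied to distance, so strength and distance are not separated here. All untreated contacts of 2 reads spanned more than 500 kb, while untreated contacts of 5 to 10 kb had a median of 18 reads. In 10 kb bins, 60392 pairs were in both lists, and their reads had a Spearman correlation of 0.81 across pairs, which are not independent replicates. Reads per contact fell with distance in both lists, which by itself raises this correlation. The median log2 ratio of these pairs after scaling was 0.59 (quartiles 0.11 and 1.03). A pair must pass the listing in both lists to count, which by itself raises this value. With no change between lists, a random split of the untreated reads gave 0.67, and the thinned untreated list against the whole one gave 0.55. Scaling on these shared pairs instead of on all reads therefore lowers every log2 ratio by 0.59, so that ratios between 0 and 0.59, those of the distance bands included, become negative. The split and the thinned lists shared 164677 and 599913 pairs on average, against 60392 observed, so they do not fix the no-change value here. Whether the 0.59 holds a change is open, and such turns of sign alone do not show that a ratio is lower.

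Chromosomes differed in their share of contact reads. Chromosome X was highest in GSI-treated cells, with 2.09% of the untreated reads and 2.86% of the GSI-treated reads, a log2 ratio of 0.45 (0.44 to 0.46). Chromosome 19 followed with 0.31 and chromosome 3 with 0.19. These 3 ratios, like those of the other 6 chromosomes above 0, turn negative when scaled on shared pairs. Chromosome 22 was lowest, with 1.77% and 1.14% of reads and a log2 ratio of -0.63 (-0.65 to -0.61). Chromosome 13 stood at -0.58, chromosome 14 at -0.50, chromosome 17 at -0.43, chromosome 16 at -0.41 and chromosome 21 at -0.39. Chromosomes 22 and 13 also had the highest shares of 50 kb windows at or below 0.5 times their untreated share, 44.6% of 513 windows and 42.3% of 130. On chromosome X this was 1.21% of 909 windows.

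**Figure D2:**
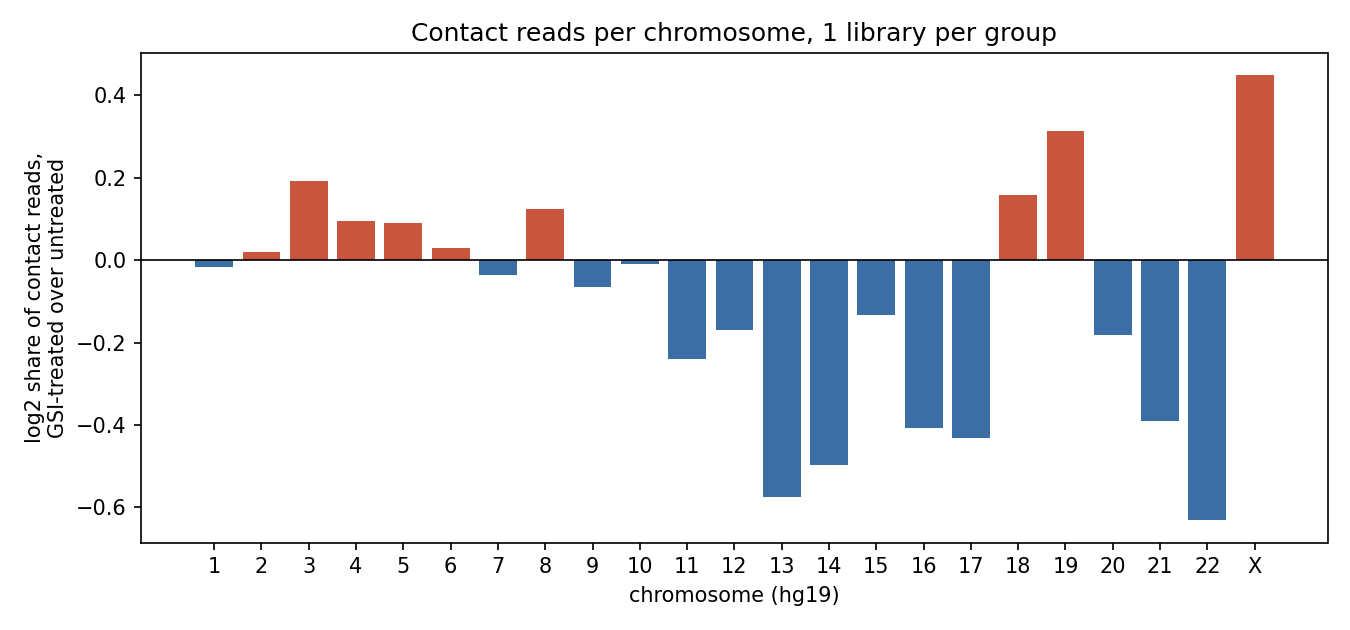
Log2 ratio of each chromosome's share of contact reads, GSI-treated over untreated (vertical axis), for chromosomes 1 to 22 and X in hg19 (horizontal axis). Bars run from 0.45 for chromosome X, which is -0.14 when scaled on shared pairs, to -0.63 for chromosome 22, with 1 library per group.

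Chromosome 19 held the densest contacts of both libraries. The block from 30 to 33 Mb carried 5.04% of all untreated read ends and 8.14% of the GSI-treated ones, 55.4 and 84.0 times the median 1 Mb window of the genome. Its log2 ratio was 0.69 (0.68 to 0.70), and 0.11 when scaled on shared pairs. Contacts inside the block carried a mean of 14.9 reads in the untreated list and 13.0 in the GSI-treated list, against 4.61 and 3.65 elsewhere. The windows on either side parted. The windows at 28 to 29 Mb and 29 to 30 Mb were higher in GSI-treated cells, at 1.04 and 1.17, while those at 33 to 34, 34 to 35 and 35 to 36 Mb stood at -0.37, -0.35 and -0.27. A second rise in read ends lay at 40 to 41 Mb, with 42196 untreated and 15705 GSI-treated ends, a log2 ratio of -0.39. Without the block, chromosome 19 had a log2 ratio of -0.55 (-0.56 to -0.54).

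**Figure D3:**
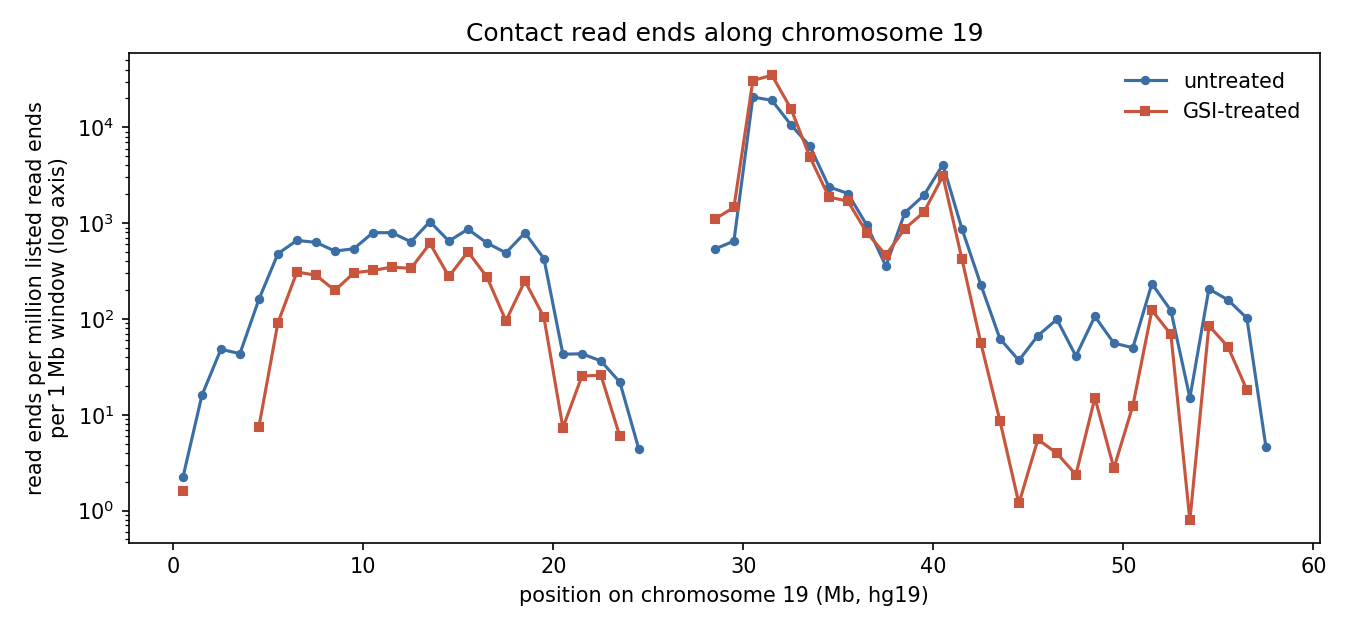
Contact read ends per 1000000 listed read ends in 1 Mb windows (vertical log axis) along chromosome 19 in hg19 (horizontal axis, Mb), for the untreated and the GSI-treated library; windows without listed ends have no point. The block at 30 to 33 Mb stands above the rest in both libraries and is higher in GSI-treated cells, by 0.69 on the log2 scale.

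The best connected anchors of both libraries lay inside this block. In untreated cells these were 31213037 to 31219510 with 503 contacts, 31166384 to 31170976 with 384, 31307934 to 31313454 with 368, 30626200 to 30632099 with 336, and 31093613 to 31099450 with 318. In GSI-treated cells they were 31166627 to 31170975 with 362 contacts, 31298855 to 31303533 with 310, 30894942 to 30900498 with 308, 31307883 to 31312640 with 298, and 31362317 to 31367872 with 291. The second of the untreated anchors and the first of the GSI-treated ones overlap, with 384 and 362 contacts. The anchors overlapping the untreated leader had 302 contacts in the GSI-treated list. Conversely, the anchors overlapping 31362317 to 31367872 had 154 contacts in the untreated list. Outside the block the best untreated anchor was at 33045077 to 33048231 on the same chromosome, with 182 contacts against 118. On chromosome 2, an anchor at 72375839 to 72379207 had 90 contacts against 51. On chromosome 8, one at 127819635 to 127823568 had 86 against 33, and one at 125438773 to 125444001 had 84 against 23. These anchors were picked as high in the untreated list, and the whole GSI-treated list held 60.2% of the untreated number of contacts. Among the best GSI-treated anchors outside the block, 66652585 to 66656801 on chromosome 2 had 59 contacts, against 71 in untreated cells. On chromosome 9, 138233616 to 138237274 had 58, against 62 in untreated cells. Over all anchors the mean was 3.70 contacts in untreated and 2.86 in GSI-treated cells. Contacts linked the anchors into 5173 connected groups in the untreated list and 12563 in the GSI-treated list. The largest group held 31233 and 23450 anchors. After thinning to about as many listed reads, the untreated list had a mean of 2.68 and 25429 groups, so the order of both measures turned. Thinning a called list only removes contacts, so this turn does not show what a shallower library would hold.

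In windows of 50 kb, 2689 of 29325 windows were at least 2-fold higher in GSI-treated cells and 4041 were at or below 0.5-fold, so 40.0% of these windows were higher. Windows entered by their ends summed over both lists, and the untreated list held more reads. Windows low in GSI-treated cells therefore passed more easily, which by itself favours lower ones. Scaled on shared pairs, 377 were higher and 8363 lower (4.31% higher), and after thinning the untreated list to about as many listed reads the numbers were 1752 and 2002 (46.7% higher). The 7 highest windows all lay on chromosome 8 between 132.6 and 139.55 Mb. The window at 132.60 to 132.65 Mb led with 87 untreated and 556 GSI-treated ends, 13.1-fold (log2 ratio 3.71, 3.38 to 4.05). Next came 136.25 to 136.30 Mb at 11.9-fold, 136.35 to 136.40 Mb at 10.2-fold, 139.35 to 139.40 Mb at 9.88-fold and 139.50 to 139.55 Mb at 9.75-fold. Those at 135.25 to 135.30 Mb and 137.10 to 137.15 Mb were 9.09-fold and 7.66-fold higher. The remaining 3 were chromosome 3 at 137.30 to 137.35 Mb (6.51-fold), chromosome 5 at 16.40 to 16.45 Mb (6.49-fold) and chromosome 9 at 25.00 to 25.05 Mb (6.42-fold). These 10 windows stayed above 0 under each alternative run for them, but by less in several. By numbers of contacts the log2 ratio was 1.36 at 139.50 to 139.55 Mb against 3.28 by reads, and 1.15 at 137.10 to 137.15 Mb against 2.93. For contacts of 20 kb or more it was 2.33 at 132.60 to 132.65 Mb, and 1.11 for the window on chromosome 5 against 2.69.

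Of the tested 50 kb windows, 35 had no listed read in the GSI-treated list, so no fold is given. In the untreated list, 0 tested windows lacked a listed read, and entry by summed ends favours this. The 10 lowest by the rule are those of the 35 with the most untreated ends, ordered through the added 0.5. A window without listed reads held no called contact, which does not show that contacts were absent. The strongest of them in untreated cells was chromosome 12 at 7.00 to 7.05 Mb with 455 ends. It was followed by chromosome 11 at 61.20 to 61.25 Mb with 379, chromosome 12 at 56.45 to 56.50 Mb with 341 and chromosome 16 at 3.55 to 3.60 Mb with 333. Chromosome 22 had 5 of the 10, at 39.10, 39.65, 39.75, 40.30 and 41.15 Mb, with 307 to 331 ends. Chromosome 21 at 44.85 to 44.90 Mb had 313.

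At 1 Mb, 58 of 2242 windows were at least 2-fold higher and 292 at or below 0.5-fold. Entry by ends summed over both lists favours lower windows here too. The lowest was chromosome 11 at 66 to 67 Mb, with 2417 untreated and 27 GSI-treated ends (log2 ratio -5.45, -6.06 to -4.91). Its neighbour at 65 to 66 Mb had 3406 and 77 ends (-4.43). Chromosome 16 at 69 to 70 Mb stood at -4.56, chromosome 4 at 1 to 2 Mb at -4.23 and chromosome 22 at 38 to 39 Mb at -4.11. Lower windows came in runs, and neighbouring windows share the read pairs that join them. On chromosome 6 all 11 windows from 6 to 17 Mb were at or below 0.5-fold, with a joint log2 ratio of -1.39, and on chromosome 11 all 10 from 57 to 67 Mb, at -1.81. Those on chromosome 14 from 67 to 76 Mb stood at -2.16 and those on chromosome 1 from 19 to 28 Mb at -1.61. The highest 1 Mb window was chromosome 11 at 23 to 24 Mb, with 922 and 1486 ends (log2 ratio 1.72, 1.60 to 1.84). It lay in a run of 5 higher windows from 21 to 26 Mb. Chromosome 7 at 88 to 89 Mb stood at 1.60 and chromosome 9 at 10 to 11 Mb at 1.48.

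Between 250 kb windows, 9 of 492 pairs were at least 2-fold higher and 54 at or below 0.5-fold. Pairs entered by their reads summed over both lists, and the untreated list held more reads. Pairs low in GSI-treated cells therefore passed more easily, which by itself favours lower ratios. The median log2 ratio of the tested pairs was -0.17. The lowest joined chromosome 22 at 39.75 to 40 Mb and 40.25 to 40.5 Mb, with 670 reads in untreated and 62 in GSI-treated cells (log2 ratio -2.40, -2.80 to -2.02). On chromosome 1, the pair at 202 and 202.5 Mb had 623 and 62 reads (-2.30), and on chromosome 11 that at 1.5 and 2 Mb had 755 and 81 (-2.19). The highest pair joined chromosome 1 at 176.75 to 177 Mb and 177.75 to 178 Mb, with 407 and 445 reads (1.16, 0.96 to 1.36). Away from chromosome 19, pairs whose windows start 1 Mb or more apart were ranked by reads. The strongest in both libraries was chromosome 8 at 142.5 to 142.75 Mb with 143.5 to 143.75 Mb. It had 2071 untreated and 1422 GSI-treated reads (0.49, 0.39 to 0.59), a ratio that turns negative when scaled on shared pairs.

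A window on chromosome 8, at 127.75 to 128.00 Mb, appeared in 3 of the 20 lowest pairs, and no other window came up more than 1 time. Its far contacts toward higher coordinates, with the windows from 128.75 to 130 Mb, had 2687 reads in 514 contacts in untreated cells and 514 reads in 139 contacts in GSI-treated cells. The log2 ratio was -1.35 (-1.49 to -1.22), or 2.56-fold lower. The partner windows at 129, 129.25 and 129.5 Mb, the pairs by which the window was picked, stood at -1.70, -1.97 and -1.56, and the others, at 128.75 and 129.75 Mb, at -0.90 and -0.45 (-0.79 to -0.12). Contacts of the same window with 128 to 128.75 Mb had 936 and 603 reads, a log2 ratio of 0.40 (0.25 to 0.55) that becomes -0.19 when scaled on shared pairs. Contacts within the partner region itself had 2217 and 1113 reads (0.04, -0.07 to 0.14). Toward lower coordinates the window had 1817 and 622 reads (-0.51). Those with 126.5 to 126.75, 126.75 to 127 and 127 to 127.25 Mb stood at -0.93, -1.08 and -1.33. Those with 127.25 to 127.5 and 127.5 to 127.75 Mb stood at 0.13 and 0.026. The windows further out, from 125.75 to 126.5 Mb, held at most 26 untreated reads each. Inside the window there were 793 and 88 reads (-2.14), while it held 63 and 64 anchors.

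**Figure D4:**
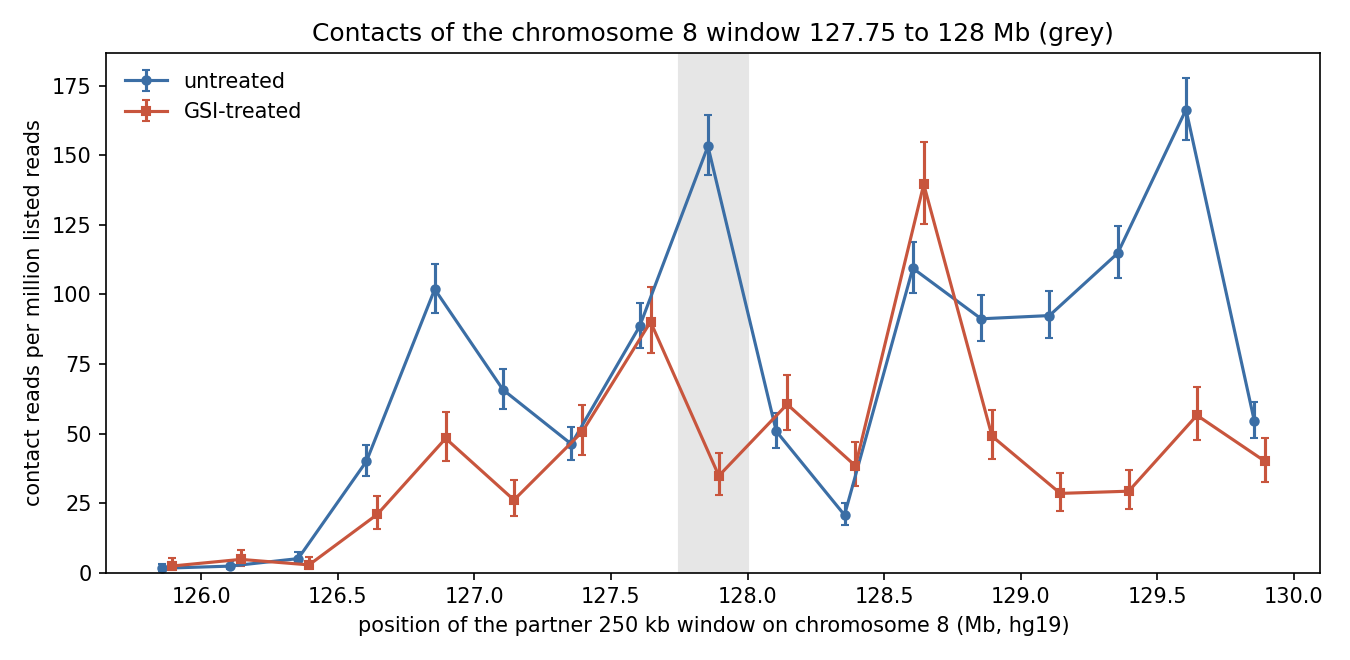
Contact reads per 1000000 listed reads (vertical axis) between the chromosome 8 window at 127.75 to 128.00 Mb (grey) and each 250 kb window around it (horizontal axis, Mb in hg19), for both libraries, with 95% Poisson intervals of counting error. The GSI-treated line lies below the untreated one from 128.75 to 130 Mb (514 against 2687 reads before scaling) and not from 128 to 128.75 Mb, where the ratio turns negative only when scaled on shared pairs.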

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

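The alternatives gave 287 values. Of these 148 stayed within the tolerance of their kind (1.5 times for counts, contacts per anchor and the GSI-treated percent of untreated contacts; the 95% counting interval for medians, shares and log2 ratios), 127 moved and 12 changed sign from a value whose interval excluded 0; the cause of these changes was not tested beyond what the scaling or filter does by construction. Many of the 148 could hardly move, so their number is no measure of robustness. The named lower windows, with 0 GSI-treated ends, had intervals without a lower end. Exact identity of anchors gave 0 under every filter. Leaving chromosomes 8 and 11 out of the scaling moved chromosome 1 only from -0.0172 to -0.0182. Alternatives on thinning to the listed reads, on lists with no change and on leaving out the contact-dense block were chosen after seeing the data. So were those on the chromosome 8 window and on combining 5 kb tolerance with another filter. An FDR of 0.01, other promoter windows and every gene-list alternative were not run, since the lists give no FDR and no gene was placed. With 4 or more reads there were 472073 untreated and 196940 GSI-treated contacts, medians of 316 and 242 kb, 34829 and 40083 connected groups, and 1471 windows higher at least 2-fold (30.4% of those past 2-fold), and log2 ratios of -1.70 and 0.70 for the far and near contacts of the chromosome 8 window. For contacts of 20 kb or more the medians were 877 and 906 kb, with 1609 higher windows (37.1%). Thinning the untreated list at the ratio of the totals left 2192429 listed reads, fewer than the 2528596 of the GSI-treated list, and gave 611806 contacts, of which the GSI-treated number was 107%, a median of 530 kb, 28986 groups, 1732 windows higher and 1822 lower (48.7% higher) and 0.18 for the near contacts. Thinning to about as many listed reads gave 644129 contacts (101%), a median of 680 kb, 25429 groups, 1752 windows higher and 2002 lower (46.7% higher), and -1.57 and 0.14 for the far and near contacts. Exact identity of anchors matched 0 contacts; matching within 5 kb gave 7.71% of untreated and 11.4% of GSI-treated contacts, within 10 kb 17.8% and 24.4%, and within 5 kb 11.7% and 23.8% at 4 or more reads, 7.39% and 10.9% at 20 kb or more, and 10.9% and 9.29% after thinning at the ratio of the totals. Shared pairs with 4 or more reads in both lists had a median log2 ratio of 0.50. Anchors joined into 25 kb windows had 16.7 and 11.6 contacts on average, at most 130 and 119, in 177 and 423 groups. By numbers of contacts, 796 windows were higher (22.01%). The shared pairs' median of 0.59 lay between the 0.55 and 0.67 of lists with no change, which shared more pairs. Scaling on shared pairs left 0 chromosomes above 0: X moved to -0.14, 19 to -0.27, 3 to -0.39, 18 to -0.43, 8 to -0.46, 4 to -0.49, 5 to -0.49, 6 to -0.56 and 2 to -0.56. It gave 377 higher and 8363 lower windows (4.31%), and -1.94 and -0.19 for the far and near contacts. Without the block in the scaling every log2 ratio was higher by 0.048, chromosomes 1 and 7 moved to 0.031 and 0.013, chromosome 10, whose interval held 0, from -0.0099 to 0.038, and 44.7% of windows past 2-fold were higher. No paired analysis was possible because each group is 1 library. Contacts of 2 reads were 28.0% of the untreated and 41.1% of the GSI-treated list.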

Other observations

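The stretch of chromosome 8 that spans its named higher 50 kb windows was higher in GSI-treated cells over several Mb, with an exception in its middle. Those named windows were picked as high and are part of its sums. From 132 to 140 Mb the joint log2 ratio was 0.46, which turns negative when scaled on shared pairs, and the windows at 136 to 137, 137 to 138 and 139 to 140 Mb stood at 1.18, 1.32 and 1.28. Of the 1 Mb windows that hold no named window, those at 133 to 134 and 138 to 139 Mb stood at 0.50 and 0.95. The window at 134 to 135 Mb, which also holds none, was lower at -0.58. It was the most contact-rich of the stretch, with 25112 untreated ends. Away from chromosome 19, the strongest single contact over 500 kb in untreated cells joined 71773742 and 72375839 on chromosome 2, over 602 kb with 65 reads. In GSI-treated cells it joined 126128247 and 126654855 on chromosome 8, over 527 kb with 37 reads, and a contact at nearly the same place had 56 reads in untreated cells. On chromosome 20, 2 contacts of GSI-treated cells shared the anchor starting at 56783686, with 36 and 33 reads over 608 and 695 kb.

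Outside the block, the 500 best connected anchors of untreated cells had a median of 37 contacts, and their counterparts in GSI-treated cells a median of 18, which is 45.9% at the median anchor (quartiles 33.3% and 59.0%). The 500 best of GSI-treated cells had a median of 22, and their untreated counterparts 30, or 131%. Anchors picked for a high number in 1 list tend to be lower in another for that reason alone, so both directions are given. The whole GSI-treated list held 60.2% of the untreated number of contacts, and both percentages have to be read against that level.

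Some tests in the following paragraphs were not set beforehand or were chosen only after the result was seen. These are the tests of depth for the number of contacts and for the 1 Mb windows, and that of the partner region. They also include the matches on single parts of the chromosome 8 window's contacts. The set of windows used for local contrast, with the share of the richest windows, is another. It followed a first set that gave -0.080 but left out low windows of the GSI-treated list. A candidate explanation for the fewer contacts in GSI-treated cells is library depth, as far as listed reads show it. When the untreated list was thinned until as many listed reads were left as in the GSI-treated list, with the same lowest read number per distance, the GSI-treated list had 1.01 times the thinned number on average over 20 draws. Listed reads depend on which contacts were called, so this match bears on the number itself and leaves depth open. The thinned lists had a median distance of 680 kb against 870 kb, so this thinning does not give the GSI-treated distances. Thinning a called list removes long contacts first, so the gap leaves depth open. Depth and an effect of the inhibitor on the number of contacts cannot be told apart, since the sequencing depth is not given.

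The 1 Mb windows differed between libraries with an SD of 0.82 in log2 ratio, and neighbouring windows went together (Pearson 0.73 across 2126 adjacent pairs, 0.15 at a spacing of 20 windows). Contacts reach 2 Mb and each read pair counts at both ends. Neighbouring windows therefore share read pairs, which by itself raises the 0.73. Thinning the listed untreated reads gave an SD of 0.166 and 0 windows at or below 0.5-fold, against 292 observed. A random loss of listed reads alone therefore does not give these differences. The thinned lists keep the untreated calls and anchors, while the anchors of the 2 real lists differ. Calling at a lower depth was not tested and stays open. Leaving the block on chromosome 19 out of the scaling raises all other windows alike, by 0.048, so the 92.5% of the 292 windows that stayed at or below 0.5-fold do not test its part. Lower enrichment at contact-rich sites cannot be told apart: local contrast (the SD of log2 ends of 50 kb windows around their 1 Mb mean) lay 0.138 above the lowest thinned list, the opposite of what was predicted for it, but that SD also takes in contact-poor windows, and the 2 richest 50 kb windows of a 1 Mb window held on average 20.98% of its ends in GSI-treated cells, against 21.89 to 21.98% in the thinned lists and 20.51% in the whole untreated list. GC content, copy number and a Notch effect were not tested and stay open.

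The far contacts of the chromosome 8 window at 127.75 to 128.00 Mb were lower in GSI-treated cells, and its near contacts toward higher coordinates were not, except when scaled on shared pairs (-0.19). Thinning the listed untreated reads gave log2 ratios of 0.097 to 0.25 in 100 draws, against -1.35 observed. These draws also keep the untreated calls, so calling at a lower depth stays open. The window was also thinned until all its contacts under 4 windows of 250 kb away matched. Its far contacts then kept 895 to 1066 reads, against 514 observed. Matched only on those toward lower coordinates they kept 910 to 1056, and only on those toward higher coordinates 1656 to 1792. Matched on contacts inside the window alone they kept 104 to 182. That last match rests on 88 GSI-treated reads in 3 contacts, against 793 untreated reads in 18. The far contacts include the 3 pairs by which the window was picked. Partner windows outside those pairs, at 128.75 and 129.75 Mb, stood at -0.90 and -0.45. None of these draws therefore decides on depth or on a loss of copies of the window. Contacts within the partner region had a log2 ratio of 0.038, which speaks against a loss of signal there. The difference was not confined to far contacts, since those inside the window (-2.14) and with 127 to 127.25 Mb (-1.33) were lower too. Far contacts toward lower coordinates, with 126.5 to 126.75 and 126.75 to 127 Mb, were lower as well (-0.93 and -1.08). A loss of some contacts of this window under the inhibitor may be a hypothesis worth a replicate, since it was found and tested on the same 2 libraries, and the genes of the region were not placed here.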
